A study of Mus musculus with 4 samples.

How the data were processed

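The data were 4 libraries of single-cell 3' RNA counts from mouse brains that carried EO771 tumours, 1 library for each combination of treatment (vehicle or SCDi) and sort (tumour or immune), each from 3 pooled mice. The deposited matrices hold raw UMI counts per gene and barcode over 32285 genes, and every deposited barcode had at least 500 UMIs. Per the submitters' processing notes the counts were made with Cell Ranger 7.1.0 on mm10, and the labels' protocol names R studio and Seurat for the steps after that. The gene annotation and whether intronic reads were counted are not given in the sources used here. Gene positions came from GENCODE M21 matched by Ensembl identifier, which placed 32235 genes and left 50 without a position.

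Barcodes with fewer than 300 genes or more than 15% mitochondrial UMIs were left out, which kept 6959 of the vehicle immune, 7453 of the vehicle tumour, 6453 of the SCDi immune and 8895 of the SCDi tumour barcodes. Doublet scores were computed per library by a reimplementation of Scrublet. Its automatic threshold failed, as it marked at most 0.0775% of barcodes, under the floor of 0.5%, so the highest scores were removed at a rate of 0.8% per 1000 barcodes, a fallback that removed 387, 444, 333 and 633 barcodes in the same order and left 6572, 7009, 6120 and 8262 cells. The libraries of each sort were clustered together with the Leiden algorithm at resolution 1.0, on 2000 variable genes, 30 principal components and 20 neighbours, which gave 24 immune and 19 tumour clusters. Clusters were named from marker lists written before the data were examined, with a marker called at a fold of 2, 3 markers needed, and thresholds on the share of cells (10% for immune and 4% for tumour clusters) that were set after the data were seen. This named 19 immune and 18 tumour clusters, 17 of them malignant, and unnamed clusters were kept out. Lymphoid cells with at least 5 UMIs of myeloid genes at over 35% of the macrophage and monocyte level, and named non-lymphoid cells with at least 3 UMIs of lymphoid genes, were left out as mixed. That rule, and the removal of Cd79b from its lymphoid genes, were chosen after the data were seen.

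For each class with at least 50 cells and 100000 UMIs in both libraries, UMIs were summed over cells and each gene's count was scaled by the class's total UMIs in that library (CPM), and the log2 ratio of SCDi over vehicle was taken with 0.5 counts added. The interval of a ratio is the exact conditional binomial 95% interval of the pair of Poisson counts, and that of a share of cells is the exact Clopper-Pearson interval. A fold against 0 counts is given as a lower bound at 3 counts over the group. There is 1 library per group, so no test across animals was run and no number of differing genes is given. The median log2 ratio of genes with at least 20 CPM in both libraries was -0.03 in malignant cells.

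The genes named in each class were set by a rule fixed before the data were examined. Among genes with at least 20 CPM in either library, without mitochondrial, ribosomal protein and predicted genes or immunoglobulin and T cell receptor segments, the rule takes the 12 highest and 12 lowest ratios in malignant cells and the 6 highest and 6 lowest in each immune class. It adds the SCD genes in every class, the 2 highest and 2 lowest members of each gene list, and Ptprc, Krt8 and Krt18 as a check of the sort. The text does not name every gene that the rule takes. The 33 gene lists were also fixed beforehand. A list's members are its genes with at least 5 CPM in either library, its interval comes from 1000 Poisson draws, and its percentile is its median's place among 10000 random lists drawn from the 100 genes nearest in expression to each member. A list in the highest or lowest 2.5% is described as standing apart, as a description of these libraries. Shares of cells with a UMI were taken on all UMIs and after thinning each cell to 2000 UMIs.

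The comparison was tested on simulated data made from the malignant counts, with 200 of 6148 genes given a known fold. The interval held the true ratio for 98.5% of genes at 1.1-fold, 97.0% at 1.5-fold and 93.9% at 2-fold. The counts were drawn as Poisson, which the interval assumes, so this checks the calculation only. It does not cover variation between cells or animals. For lists, the ratios of 9476 genes were shuffled among genes of similar expression. Of 230 such lists, 3.48% stood apart with no difference put in and 97.8% with a 1.2-fold difference. Shuffling removes shared regulation of list members, so the first rate does not cover it.

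Alternatives tried were all deposited barcodes, a stricter filter (500 genes, 10% mitochondrial UMIs), no doublet removal, Leiden resolutions 0.5 and 2.0, all kept cells of the tumour libraries, scaling by the median of ratios, the mean of each cell's own CPM, no filter or 20 CPM for list members, 5 counts added, thinning to 1000 and 5000 UMIs, and malignant cells without Mki67 or Top2a. The mean over clusters with at least 50 cells in both libraries, the same mean without clusters whose chromosome 19 differed by 0.15 or more between the libraries (for Scd1 and Scd2), list members at 20% or more of the highest immune class, mixed cells kept, and Cd79b among the lymphoid genes were added after the data were seen. Mast cells or basophils were not compared because they had 40 and 13 cells. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.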

Results

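The series asks what inhibition of stearoyl-CoA desaturase (SCD), the enzyme that puts a double bond into saturated fatty acids, does to the cancer cells and the immune cells of breast cancer growing in the brain. Female C57BL/6 mice carried intracranial tumours of EO771 cells, a mouse mammary cancer line that here expressed GFP, and received vehicle or an SCD inhibitor (SCDi, compound and dose not given in the sources used here) for 14 days. Brains of 3 mice per treatment were pooled and sorted into live GFP-positive CD45-negative tumour cells and live CD45-positive GFP-negative immune cells, and each sort gave 1 droplet library of single-cell 3' RNA counts. The vehicle immune library held 7332 barcodes and 135851178 UMIs, with medians of 15293.5 UMIs and 3710.5 genes per barcode. The SCDi immune library held 6777 barcodes and 141068797 UMIs, with medians of 16548 UMIs and 3827 genes. The vehicle tumour library held 7713 barcodes and 307846497 UMIs, with medians of 41124 UMIs and 6496 genes. The SCDi tumour library held 9034 barcodes and 329888529 UMIs, with medians of 36680.5 UMIs and 6226.5 genes. There is 1 pooled library per group and so no replicate. Every comparison below describes these libraries, intervals are 95% intervals that cover counting error only, and no difference was tested across animals.

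Epithelial and leukocyte markers separated the sorts. Krt8, a keratin of simple epithelia, had a UMI in 98.0% (97.6 to 98.3) of the 7009 kept vehicle tumour cells and in 96.4% (96.0 to 96.8) of the 8262 kept SCDi tumour cells. The shares were 2.18% and 3.17% in the immune cells, at median depths of 40929, 36110, 15294 and 16558 UMIs. Thinned to 2000 UMIs per cell, the shares were 92.0% and 90.5% in the tumour sorts and 0.631% and 0.516% in the immune sorts. Krt18, the usual partner of Krt8, had a UMI in 16.1% and 17.2% of the tumour cells and in 0.243% and 0.180% of the immune cells. Ptprc, which encodes CD45, had a UMI in 96.6% and 98.1% of the immune cells (77.7% and 76.5% after thinning), in 7 vehicle tumour cells (0.0999%) and in 0 SCDi tumour cells, which allows a share of up to 0.0446%.

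The comparison of the tumour sorts asks how malignant cells differed under SCD inhibition. In 7200 malignant cells of the SCDi library against 6356 of the vehicle library, transcripts of the desaturases themselves, of cholesterol and fatty acid synthesis enzymes and of the cell cycle were more abundant. Transcripts of the hypoxia response, of MHC class I presentation and of cell adhesion were less abundant. Scd2, a desaturase prominent in brain and in proliferating cells, stood at 49.8 CPM (13820 UMIs) in vehicle and 80.02 CPM (23371 UMIs) in SCDi, 1.61-fold higher (log2 ratio 0.68, 0.65 to 0.71). Scd1, the main desaturase of liver and fat, stood at 22.4 and 28.8 CPM (6228 and 8403 UMIs), 1.28-fold higher (log2 ratio 0.36, 0.31 to 0.41). Both genes lie on chromosome 19 of mm10, Scd2 (ENSMUSG00000025203) at 44293674 to 44306864 on the plus strand and Scd1 (ENSMUSG00000037071) at 44394455 to 44407879 on the minus strand. The other members were rare: Scd4 had 103 and 195 UMIs (log2 ratio 0.84, 0.50 to 1.21) and Scd3 had 25 and 41 (0.63, -0.11 to 1.42).

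Lipid synthesis genes were higher too in the summed cells. Of 23 measured cholesterol synthesis genes, 20 were higher in the SCDi library, with a median log2 ratio of 0.26 (0.24 to 0.29) that exceeded every random list of matched expression (percentile 100). As a mean over clusters that median was 0.058, with 6 clusters higher and 5 lower, and it parted from Scd2 in clusters 0, 1 and 8 (-0.19, -0.18 and -0.25 against 0.73, 0.38 and 0.42 for Scd2). Acat2, which makes the acetoacetyl-CoA that enters the mevalonate pathway, stood at 25.8 CPM in vehicle and 39.3 in SCDi (log2 ratio 0.60). Pmvk, phosphomevalonate kinase, stood at 58.1 and 85.7 CPM (0.56), while Idi1 (-0.059) and Hsd17b7 (-0.056) were lowest. Of 19 fatty acid synthesis genes, 14 were higher (median 0.18, 0.12 to 0.20, percentile 100), led by the elongase Elovl6 at 41.5 and 54.6 CPM (0.40) and the acyl-CoA synthetase Acsl3 (0.29). The chain elongation enzymes Tecr (-0.14) and Hsd17b12 (-0.064) lay at the other end. Fatty acid oxidation genes leaned the other way, with 11 of 15 lower (median -0.18, -0.20 to -0.13, percentile 0.85). Angptl4, an inhibitor of lipoprotein lipase, had a log2 ratio of -0.33 and the dehydrogenase Acadl -0.31, while Hadhb of the trifunctional protein had 0.11. With list members at 20 CPM, neither fatty acid list stood apart any longer (synthesis 0.082, percentile 96.6, and oxidation -0.14, percentile 12.3), and as a mean over clusters the oxidation median was -0.059 (percentile 8.18). Lipid droplet genes were lower in 7 of 10, without standing apart from random lists (median -0.14, percentile 7.75), although they did with members at 20 CPM (-0.26) and as a mean over clusters (-0.12). Plin2, the main droplet coat protein, stood at 115 and 72.3 CPM (-0.66) and Hilpda, which restrains droplet lipolysis, at 59.2 and 45.1 (-0.39). The list of LXR targets had a median of 0.082 (percentile 97.0), with the sterol exporter Abcg1 at 0.23 and the lysosomal cholesterol transporter Npc1 at -0.51, and stood apart in cells without Mki67 or Top2a (0.15).

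**Figure D1:**
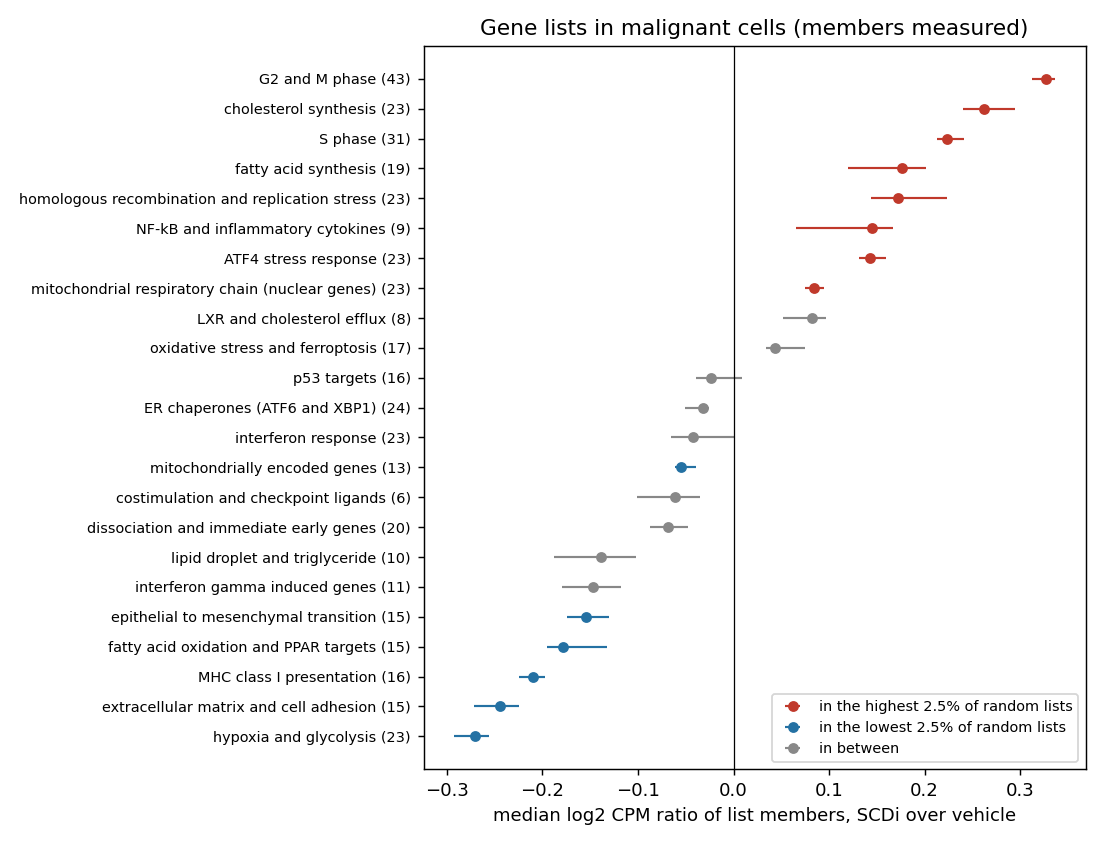
Median log2 ratio of SCDi over vehicle CPM (horizontal axis) for each gene list in malignant cells (vertical axis), with bars for the 95% interval from Poisson draws, the number of measured genes in parentheses, and colour for lists in the highest or the lowest 2.5% of random lists. Cell cycle and cholesterol synthesis genes lie at the high end and hypoxia genes at the low end.

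Genes of DNA replication and division were more abundant in the SCDi library. All 43 measured G2 and M phase genes were higher (median 0.33, 0.31 to 0.34, percentile 100), from Cdca3 (0.50) and the mitotic activator Cdc20 (0.49) down to Ckap5 (0.043). So were 30 of 31 S phase genes (median 0.22, 0.21 to 0.24, percentile 100), led by the nucleotide synthesis genes Tyms and Rrm2 (0.46 each) with Cdt1 at -0.070. Homologous recombination genes were higher in 19 of 23 (median 0.17, 0.14 to 0.22, percentile 100), with the exonuclease Exo1 at 0.44, Rad51ap1 at 0.39, Fanca at -0.22 and the checkpoint kinase Atr at -0.11 (0.0501 as a mean over clusters). Counted per cell, Mki67 or Top2a had a UMI in 32.6% (31.4 to 33.8) of vehicle malignant cells and in 40.2% (39.1 to 41.3) of SCDi malignant cells thinned to 2000 UMIs, which left out 7 and 8 shallower cells. Before thinning the shares were 80.3% and 90.1%, at median depths of 42829 and 38350 UMIs. In neutrophils of the immune libraries, which do not divide, the thinned share was 1.45% (1 of 69 cells) in vehicle and 0 of 52 cells in SCDi, which allows up to 6.85%, at median depths of 3670 and 4661 UMIs. The background in the tumour libraries was not measured and can differ from this.

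Stress programmes differed among themselves. ATF4 targets, which answer amino acid shortage and other stresses, were higher in 20 of 23 (median 0.14, 0.13 to 0.16, percentile 100), led by the serine synthesis enzyme Psph (0.54) and the stress-induced chromatin protein Nupr1 (0.36), with the cystine transporter Slc7a11 at -0.10 (0.17 as a mean over clusters) and Sars at -0.049. ER chaperone genes did not stand apart (median -0.032, percentile 30.9), with Creld2 at 0.23 and the ER-associated degradation factor Sel1l at -0.37, but stood high in cells without Mki67 or Top2a (0.10, percentile 99.9). The oxidative stress and ferroptosis list had a median of 0.044 (percentile 90.8), from Gclm of glutathione synthesis (0.34) to the transferrin receptor Tfrc (-0.31), and stood high as a mean over clusters (0.067) and in cells without Mki67 or Top2a (0.10). The p53 targets had a median of -0.024 (percentile 64.7), from the pro-apoptotic Bax (0.22) to Mdm2 (-0.29). NF-kB and cytokine genes had a median of 0.14 (0.066 to 0.17, percentile 99.0) over 9 members, 5 of them higher, with the inhibitor Nfkbia at 0.30 and the chemokine Ccl2 at -0.21. This list no longer stood apart with no filter on members (0.047, percentile 86.7) or in cells without Mki67 or Top2a (0.11, percentile 91.15). Nuclear genes of the respiratory chain were higher in 17 of 23 (median 0.084, 0.075 to 0.094, percentile 98.1; Atp5g1 0.25, Sdha -0.12), but did not stand apart by the mean of each cell's own CPM (0.061) or in cells without Mki67 or Top2a (0.049). Mitochondrially encoded genes were lower in 9 of 13 (median -0.055, -0.062 to -0.039, percentile 2.07; mt-Nd1 0.13, mt-Nd5 -0.41). Their median was 0.0038 as a mean over clusters and 0.0495 (percentile 92.1) in cells without Mki67 or Top2a, and no longer stood apart with all deposited barcodes (-0.044, percentile 3.90). Dissociation and immediate early genes had a median of -0.069 (percentile 10.6), with Socs3 at 0.67 and Klf6 at -0.43, and stood low as a mean over clusters (-0.13).

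The hypoxia and glycolysis list had the lowest median, with 19 of 23 genes lower in the SCDi library (-0.27, -0.29 to -0.26, percentile 0). Bnip3, a mitophagy receptor induced by HIF-1, stood at 30.1 and 12.9 CPM (log2 ratio -1.22) and Ndrg1 at 170 and 112 (-0.60), while the housekeeping glycolytic gene Gapdh was at 0.034. MHC class I presentation genes were lower in 15 of 16 (median -0.21, -0.22 to -0.20, percentile 0.02), with the light chain B2m at 931 and 658 CPM (-0.50), the heavy chain H2-K1 at 251 and 183 (-0.46) and the proteasome activator Psme2 at 0.083. Type I interferon response genes showed no common direction (10 of 23 higher, median -0.042, percentile 55.2; Isg15 0.21, Rsad2 -0.53), but stood high as a mean over clusters (0.23) and low in cells without Mki67 or Top2a (-0.14). Interferon gamma induced genes were lower in 9 of 11 without standing apart (median -0.15, percentile 7.11), with Nlrc5, the transactivator of MHC class I genes, at -0.49, and stood low as a mean over clusters (-0.20) and in cells without Mki67 or Top2a (-0.27). MHC class II genes were too few for a median. Matrix and adhesion genes were lower in 13 of 15 (median -0.24, -0.27 to -0.23, percentile 0.01), including the integrins Itgb3 (-0.66) and Itgav (-0.55) but not the protease inhibitor Timp1 (0.22). Mesenchymal transition genes were lower in 11 of 15 (median -0.15, -0.17 to -0.13, percentile 0.71), with Itgb1 at 428 and 301 CPM (-0.51), Zeb2 at -0.36 and Snai1 at 0.11, but did not stand apart in cells without Mki67 or Top2a (-0.062, percentile 10.75). Costimulation and checkpoint ligands had a median of -0.061 (percentile 49.98), with the poliovirus receptor Pvr at 54.4 and 35.5 CPM (-0.62), and stood low as a mean over clusters (-0.14).

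Among single genes with at least 20 CPM, Piwil4, a piRNA pathway protein, was lowest at 48.1 CPM in vehicle and 11.8 in SCDi (log2 ratio -2.03, -2.09 to -1.98). It was followed by the matrix proteoglycan Prelp (-1.45), the small heat shock protein Cryab at 276 and 117 CPM (-1.23), Bnip3, Osbp2 (-1.04), the chitinase Chit1 (-0.99), Clip4 (-0.92), the protease Klk6 (-0.92) and the protease inhibitor Slpi (-0.91). Next came the muscle atrophy ubiquitin ligase Fbxo32 (-0.88), the calcium pump Atp2b4 (-0.85) and the EGF receptor ligand Areg (-0.80). The highest ratios were smaller: the histone Hist1h2ap (0.87), the secreted skin protein Dmkn (0.86), Irak1bp1 (0.85), the cell cycle phosphatase Cdkn3 at 29.4 and 51.6 CPM (0.81), the linker histone H1f0 at 73.5 and 126 (0.78), the transcription factor Hand1 (0.74) and Hist1h2bc (0.71). Below them came Scd2, the cytokine signalling inhibitor Socs3 (0.67), Ifi213 (0.63), Sapcd2 (0.63) and the ER retrieval receptor Kdelr3 (0.62, but -0.033 as a mean over clusters). Each of these genes had UMIs in at least 1344 cells of each library.

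Different clusters held most of the malignant cells of each library: clusters 0, 1 and 3 held 60.1% of the vehicle cells, and clusters 7, 6, 4, 9 and 5 held 55.3% of the SCDi cells. In 7 of the 17 malignant clusters at least 80% of the cells came from 1 library. The mostly SCDi clusters among them held 55.7% of SCDi malignant cells, and also 14 to 123 vehicle cells each. The mostly vehicle cluster 16 held 1.86% of vehicle malignant cells. Each of the 7 differed from the other malignant cells by the expression of a whole chromosome, for instance chromosome 8 in clusters 6 and 7 (median log2 ratio -0.26 in both) and chromosome X in the vehicle cluster 16 (-0.86), and so did clusters 3 and 4, which held more of both libraries. Clusters 13, 14 and 15 also differed in this way, and their vehicle cells lay at 0.17 to 0.34 of the vehicle median depth. So did cluster 18, with 19 vehicle and 23 SCDi cells, where the SCDi cells lay at 0.23 of the SCDi median depth although the median over all its cells was 38910 UMIs. Averaged over the 11 clusters with at least 50 cells in both libraries, Scd2 remained higher (0.57; 9 of 11 clusters higher, and 0.47 without cluster 9, whose chromosome 19 differed by 0.23 between the libraries) and hypoxia genes were lower in 11 of 11 clusters, whereas the cholesterol synthesis median was 0.058. A further cluster that could not be named, 8.67% of vehicle and 12.4% of SCDi tumour cells, and an endothelial cluster of 45 and 34 cells were kept out by thresholds set after the data were seen.

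**Figure D2:**
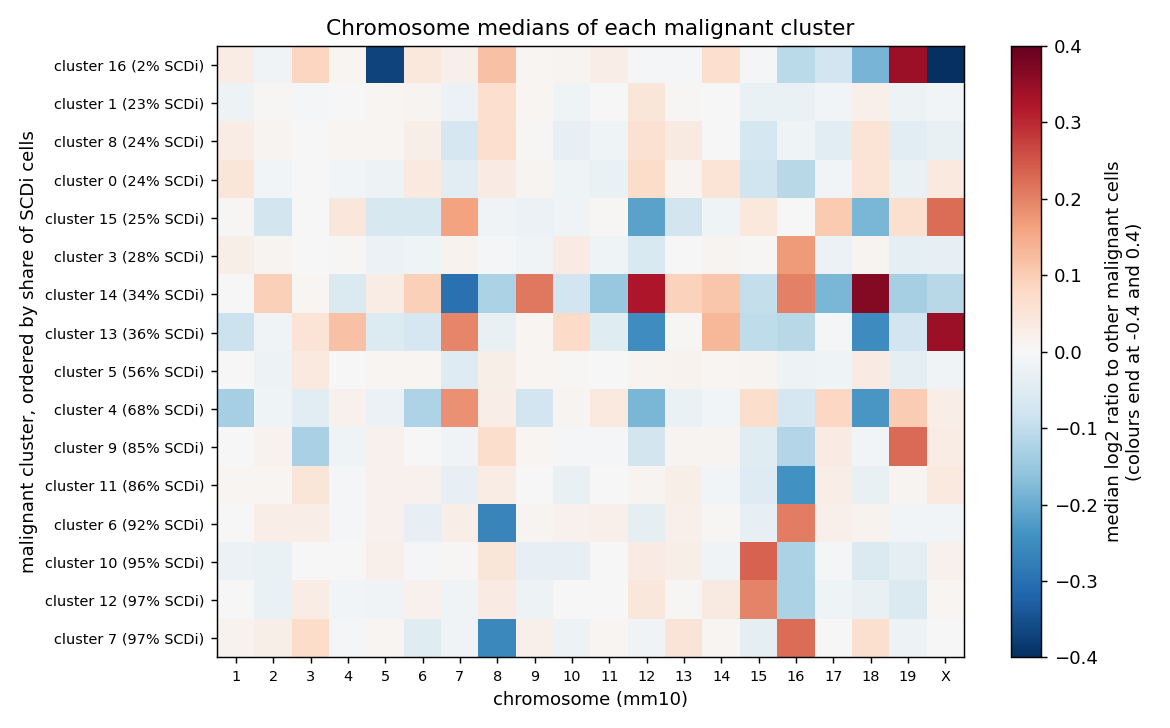
Median log2 ratio of each chromosome's genes in a malignant cluster against the other malignant cells (colour), by chromosome (horizontal axis) and by cluster with its percent of cells from the SCDi library (vertical axis). Clusters 6 and 7 share a low chromosome 8, clusters 10 and 12 a high chromosome 15, and cluster 16 has a low chromosome X.

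The comparison of the immune sorts asks whether the leukocytes around the tumour differed in kind. Macrophages and microglia made up more, and migratory dendritic cells and T cells less, of the sorted CD45-positive cells in the SCDi library, over 5581 named immune cells in vehicle and 5106 in SCDi. Macrophages were 38.4% (37.1 to 39.7) in vehicle and 44.0% (42.6 to 45.4) in SCDi, a difference of 5.61 percentage points (3.73 to 7.49). Microglia, the resident macrophages of the brain, were 5.68% (5.09 to 6.32) and 8.17% (7.43 to 8.95), a difference of 2.49 points (1.51 to 3.47). Migratory dendritic cells, which carry antigen to lymph nodes, were 8.40% (7.69 to 9.16) and 4.94% (4.36 to 5.57), a difference of -3.47 points (-4.42 to -2.52). T cells were 7.29% (6.62 to 8.01) and 4.88% (4.30 to 5.50), a difference of -2.42 points (-3.33 to -1.50). Monocytes were 24.1% and 23.8% (-0.27 points, -1.90 to 1.37), but with all deposited barcodes 25.2% and 27.2%, a difference of 2.004 points (0.32 to 3.69) in the other direction. A difference was not detectable at this depth for type 2 conventional dendritic cells at 6.15% and 5.39% (-0.76, -1.66 to 0.14) or NK cells at 3.62% and 3.21% (-0.41, -1.11 to 0.30), both lower under every alternative. Nor was it for B cells at 2.45% and 2.39%, plasmacytoid dendritic cells at 1.92% and 1.90% and neutrophils at 1.31% and 1.08%, each with an interval of the difference that includes 0. Mast cells or basophils were few, 40 and 13 cells (0.717% and 0.255%, a difference of -0.46 points, -0.75 to -0.19). The sort and the recovery of cells after dissociation set which cells enter these shares. Unnamed clusters with 12.3% of vehicle and 14.2% of SCDi immune cells, and cells with both lymphoid and myeloid transcripts (2.74% and 2.32%), were left out by thresholds set after the data were seen. The latter rule fell mostly on microglia (77 vehicle and 67 SCDi cells left out, 317 and 417 kept) and B cells (49 and 24 left out, 137 and 122 kept). With mixed cells kept, the microglia difference was 2.38 points and the B cell difference -0.45. Without doublet removal the macrophage difference was 2.65 points, the microglia difference 3.78 and the monocyte difference 1.37. Cells were clustered anew in that setting, and unnamed clusters held 23.5% of vehicle and 28.3% of SCDi immune cells. The doublets and the change in naming cannot be told apart there.

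**Figure D3:**
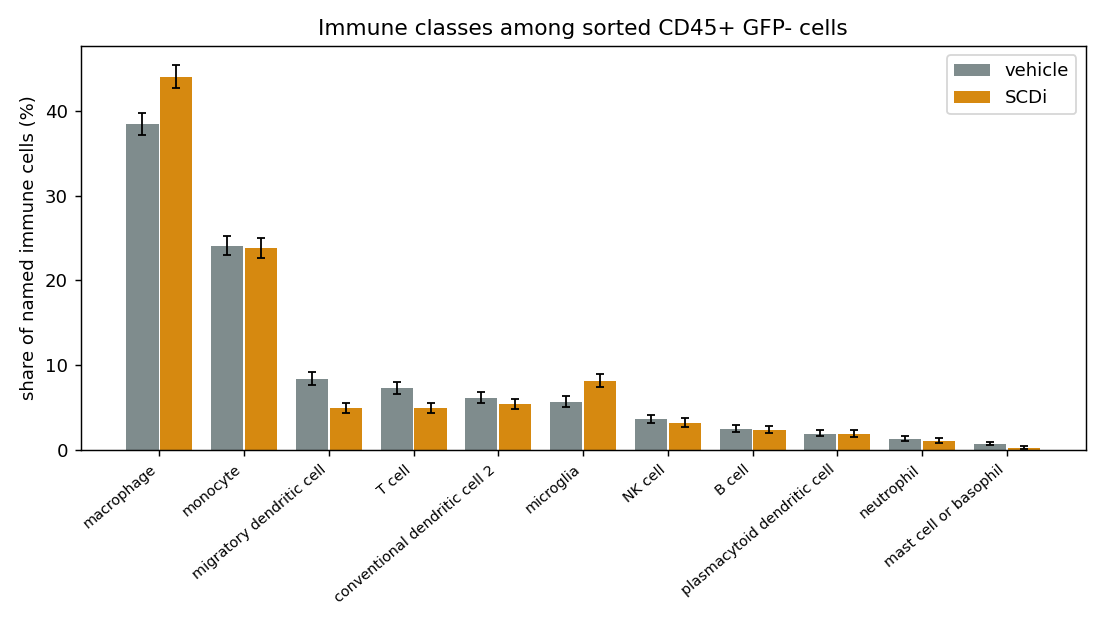
Percent of named immune cells (vertical axis) in each class (horizontal axis) in the vehicle and SCDi immune libraries, with exact binomial 95% intervals that cover counting error only. Macrophages and microglia are higher, and migratory dendritic cells and T cells lower, in the SCDi library.

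Scd2 was higher in the SCDi library in several immune classes too. In macrophages it stood at 26.6 CPM in vehicle and 40.6 in SCDi (log2 ratio 0.61, 0.50 to 0.72), and in monocytes at 11.0 and 20.9 (0.93, 0.69 to 1.16). In T cells it stood at 38.0 and 59.7 (0.65, 0.41 to 0.90). Type 2 conventional dendritic cells had it at 34.9 and 52.8 (0.60, 0.33 to 0.86). B cells had it at 43.5 and 74.9 (0.78, 0.36 to 1.22), in 30 and 35 cells. The B cell value rests partly on 1 SCDi cell, which held 22.97% of the SCDi UMIs, against 13.04% in the top vehicle cell. The difference was not detectable at this depth in microglia (0.18, -0.06 to 0.41), NK cells (0.24, -0.23 to 0.70), plasmacytoid (0.22, -0.23 to 0.68) or migratory dendritic cells (0.41, -0.23 to 1.03), and neutrophils had 1 UMI in each library. Scd1 was abundant in B cells, where it was lower at 211 and 154 CPM (-0.45, -0.68 to -0.23), and rare in the other immune classes. Cholesterol synthesis genes stood in the highest 2.5% of random lists in 5 of the 10 compared immune classes and in the lowest in 1, microglia.

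Macrophages of the SCDi library had less hypoxia and MHC class II transcript and more interferon response transcript. Arg1, the arginase of alternatively activated macrophages, was the lowest gene at 104 CPM in vehicle and 20.5 in SCDi (5.08-fold lower, log2 ratio -2.34, -2.44 to -2.24; 430 and 132 cells with a UMI), while the list of alternative activation genes it belongs to did not stand apart (10 of 14 lower, median -0.16, -0.20 to -0.049, percentile 2.5, on the edge of the lowest range). It was followed by Junos (-1.45), the elastase Mmp12 at 85.6 and 31.6 CPM (-1.44), Hilpda (-1.31), the angiogenic factor Vegfa at 32.9 and 13.3 (-1.31) and the protease Ctsk (-1.24). Among the highest were the lectin receptor Clec4b1 (1.505), Cd300e (1.496), the cyclin Ccnd2 (1.05), Dynlt1f (0.89) and Serpina3g (0.85). Interferon response genes were higher in 25 of 26 (median 0.27, 0.25 to 0.29, percentile 100; Oas1a 0.74, Irf7 0.44). Interferon gamma induced genes were higher in 16 of 20 (median 0.20; Gbp2 0.56, Ciita -0.81), MHC class I genes in 18 of 19 (median 0.15; Psme1 0.35) and respiratory chain genes in 23 of 23 (median 0.18). Cholesterol synthesis genes were higher in 13 of 16 (median 0.16, 0.10 to 0.22; Fdps 0.50) and S phase genes in 15 of 19 (median 0.14). The interferon gamma list no longer stood apart as a mean over clusters (0.059), the MHC class I list without doublet removal (0.11) and the S phase list with members at 20 CPM (0.0039). MHC class II genes were lower in 10 of 10 (median -0.32, -0.42 to -0.25, percentile 0.01), with their transactivator Ciita at 47.6 and 27.1 CPM and H2-Eb1 at 1909.8 and 1314 (-0.54). Hypoxia genes were lower in 19 of 22 (median -0.26; Bnip3 -0.47), oxidative stress genes in 14 of 19 (median -0.20; Ptgs2 -0.51). Disease-associated microglia genes were lower in 13 of 20 (median -0.18; Igf1 -1.13, Apoe -0.43) and dissociation genes in 22 of 22 (median -0.27; Hsph1 -1.06). Macrophage clusters 2 and 1 held most cells in both libraries, 37.4% and 31.5% in vehicle and 24.9% and 34.0% in SCDi. Cluster 6 held 11.4% in vehicle and 19.4% in SCDi, and cluster 3 held 19.7% and 21.7%. The mix of macrophage clusters therefore differed between the libraries.

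In monocytes cholesterol synthesis was the list with the highest median, with 16 of 17 genes higher (0.57, 0.40 to 0.66, percentile 100), led by the demethylase Cyp51 at 19.8 and 37.4 CPM (0.92) and the farnesyl diphosphate synthase Fdps at 28.7 and 53.05 (0.89). Lipoprotein lipase Lpl at 21.3 and 57.8 CPM (1.44), the secreted phosphoprotein Spp1 (0.96), Scd2 and Nos2 (0.84) were the other genes at the high end, although 19.96% of the SCDi Lpl UMIs lay in 1 cell. The dendritic lectin Cd209a (-1.998), Hilpda (-1.33), Hspa1a (-1.22), Slpi at 1139 and 519 CPM (-1.13), Pecam1 (-1.12) and Pf4 (-1.10) were lowest. Fatty acid synthesis (median 0.10), respiratory chain (0.11) and mitochondrially encoded genes (0.21, 13 of 13 higher) also stood high. At the other end 8 lists stood low, among them alternative activation (-0.22; Ccl24 -1.01, in 53 and 40 cells, Mrc1 -0.86), dissociation (-0.19), mesenchymal transition (-0.15), hypoxia (-0.13) and LXR targets (-0.13). Without doublet removal alternative activation (-0.066), mesenchymal transition (-0.098), hypoxia (-0.028) and LXR genes (-0.11) no longer stood apart, nor did fatty acid synthesis genes with members at 20 CPM (0.049). Clusters 0, 7 and 14 held the monocytes of both libraries.

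Microglia of the SCDi library had less MHC class II and interferon gamma induced transcript. Most macrophage and monocyte markers were lower in the same cells (median -0.74 over 15 markers, from Pf4 at -2.28 to Ms4a7 at 0.19). MHC class II genes were lower in 11 of 12 (median -0.77, -1.005 to -0.67, percentile 0), with Ciita at 22.8 and 5.36 CPM (-2.08) and H2-Eb1 at 722 and 218 (-1.73). Interferon gamma induced genes were lower in 19 of 20 (median -0.57; Gbp5 -1.09) and MHC class I genes in 19 of 19 (median -0.26; Psmb9 -0.44), although the MHC class I median was 0.00086 in cluster 11 and -0.71 in cluster 13. Homeostatic microglia genes were higher in 15 of 18 (median 0.19, 0.17 to 0.21, percentile 100), led by the Fc receptor-like Fcrls at 433 and 784 CPM (0.86) and Gpr34 (0.59). Their median was 0.049 as a mean over clusters, with -0.13 in cluster 11 and 0.26 in cluster 13. Type I interferon response genes were higher in 19 of 26 (median 0.33; Oas1a 0.76), although the latter median was -0.011 when each cell counted the same and -0.042 as a mean over clusters. Lower genes included the chemokine Ccl8 at 270 and 58.4 CPM (-2.21), Thbs1 (-1.97) and the mannose receptor Mrc1 at 79.4 and 20.5 (-1.95). Lower too were Slpi (-2.66) and Pf4 (-2.28), with 59.6% and 63.6% of their vehicle UMIs in 1 cell. Higher genes were Hist1h2ap (2.02), Il12b (1.55, in 9 and 12 cells), Ifitm10 (1.21), Cxcl13 (1.14, 73.9% of the vehicle UMIs in 1 cell), Chst8 (0.99) and Sox4 (0.99). Clusters 11 and 13 held 42.0% of the vehicle microglia each, and cluster 13 held 57.6% and cluster 11 held 31.7% of the SCDi microglia.

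The dendritic cell subsets were each compared between the libraries, not with each other. In migratory dendritic cells classical activation genes were higher in 12 of 12 (median 0.59; Fcgr1 1.30 with 32.7% of the SCDi UMIs in 1 cell, Il12b 1.24 at 153 and 361 CPM). Costimulation genes were higher in 11 of 14 (median 0.43; the T cell costimulator Cd40 at 237 and 366 CPM, 0.63) and NF-kB genes in 15 of 17 (median 0.38), the latter without standing apart for members near their highest class (0.11, percentile 95.7). Selenom (-1.86) and Sec24d (-1.40) were lowest. Of the highest genes, Acod1 (5.31) and Ccl3 (3.09) had 96.5% and 81.8% of their SCDi UMIs in 1 cell, and Egr1 (2.54) and Arhgap15 (2.20) followed. In type 2 conventional dendritic cells S phase genes were higher in 17 of 19 (median 0.69; Pola1 0.83) and MHC class II genes in 10 of 12 (median 0.15; H2-DMb2 0.73), but the S phase list no longer stood apart by the mean of each cell's own CPM (0.20, percentile 92.8). Dscam (2.39, in 7 and 23 cells), Maf (1.79), Spp1 (1.71) and Ltb (1.51) were among the highest genes and Mctp2 (-2.39) among the lowest. The haemoglobin genes at the low end came from at most 3 vehicle cells. In plasmacytoid dendritic cells interferon response genes were higher in 23 of 26 (median 0.44; Oas1a 1.88) and cholesterol synthesis genes in 20 of 23 (median 0.33; Fdps at 97.9 and 230 CPM, 1.23), and dissociation genes lower in 18 of 21 (median -0.62). Cxcl10 (2.92), Ccl2 (2.72) and Ccl12 (2.22) were among their highest genes but were lower (-0.25, -0.48 and -0.85) without doublet removal.

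T cells of the SCDi library had more S phase and effector transcript in their summed RNA while making up a smaller share of leukocytes. The shares of cells with a UMI were not higher for cycling or granzyme B genes. Thinned to 2000 UMIs, they were 24.3% in vehicle and 20.6% in SCDi for Mki67 or Top2a, and 33.0% and 31.3% for Gzmb. S phase genes were higher in 31 of 31 (median 0.52, 0.44 to 0.57, percentile 100; Ung 1.40), cholesterol synthesis genes in 19 of 22 (median 0.35, 0.20 to 0.53; Idi1 1.14, Cyp51 0.89). Respiratory chain genes were higher in 22 of 23 (median 0.22) and cytotoxic effector genes in 13 of 20 (median 0.24, 0.15 to 0.38, percentile 100), a median that was 0.0902 as a mean over clusters and did not stand apart for members near their highest class (0.15, percentile 94.8). Gzmk was at 1.22 (in 27 and 30 cells) but Ifng at -1.001 (47.03% of the vehicle UMIs in 1 cell). Exhaustion genes (median -0.12, percentile 17.0; the inhibitory receptor Lag3 -0.78), naive and memory genes (-0.17, percentile 12.97) and activation genes (-0.14, percentile 18.3; the tissue residency receptors Cxcr6 -1.17 and Itgae -1.11) did not stand apart. The p53 targets were low (median -0.23, percentile 1.49) but not with all deposited barcodes (-0.13, percentile 20.8). Xcl1, a chemokine that attracts cross-presenting dendritic cells, was at 83.2 and 426 CPM (2.36, in 42 and 53 cells), Hist1h2ap at 2.11, Penk at 2.02 and Polr2l at 1.74. Ncr1 (2.37) rested on 10 and 9 cells and Gzmc (1.76) on 1 cell for 73.4% of its SCDi UMIs. At the low end Serpinb9b (-5.34, in 10 and 2 cells), Gzmf (-4.01) and Ccl1 (-3.81) had 67.4%, 95.1% and 79.4% of their vehicle UMIs in 1 cell, and Gzmf was higher (0.18) with all deposited barcodes. They were followed by Htr7 (-3.39), Serpinb1a (-1.99) and the transcription factor Zbtb16 (-1.94). In NK cells 8 lists stood low and none high, among them activation (median -0.31; Il2ra -2.02), exhaustion (-0.23; Havcr2 -2.57, in 16 and 5 cells, Ctla4 at 180 and 44.7 CPM, -1.995) and dissociation genes (-0.28). Exhaustion and dissociation genes no longer stood apart by the mean of each cell's own CPM (percentiles 4.64 and 2.69), nor did activation genes for members near their highest class (percentile 11.9). Cytotoxic effector genes did not stand apart (median 0.065, percentile 83.4). The granzymes Gzmd (-6.28) and Gzme (-6.14) came from 9 and 12 vehicle cells, and Gzmg, at least 66.5-fold lower over the group, from 3. The granzyme Gzmf was the highest gene, at 120.25 and 590.3 CPM (2.29) in 5 and 2 cells, followed by Osgin2 (1.97, in 9 and 21 cells) and Serpina3f (1.84, in 15 and 20 cells).

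B cells of the SCDi library had more mitotic transcript, with 42 of 43 G2 and M phase genes higher (median 0.92, 0.79 to 1.13; Cenpf at 11.4 and 58.2 CPM, 2.32, in 3 and 8 cells) and homologous recombination genes higher in 16 of 21 (median 0.45), the latter with a median of -0.029 (percentile 48.3) for members at 20 CPM. Thinned to 2000 UMIs, Mki67 or Top2a had a UMI in 4.69% (1.74 to 9.92) of vehicle and 6.96% (3.05 to 13.2) of SCDi B cells. Unthinned the shares were 10.9% (6.26 to 17.4) and 21.3% (14.4 to 29.6), and both pairs of intervals overlap. B cells of the SCDi library had less MHC class II transcript (11 of 12 lower, median -0.42, H2-Oa at -0.99), which did not stand apart by the mean of each cell's own CPM (-0.039). Their highest genes, S100a8, S100a9 and Retnlg, came almost wholly from 1 SCDi cell. In neutrophils, with 73 and 55 cells, interferon gamma induced genes were lower in 20 of 21 (median -1.56, -1.72 to -1.20), hypoxia genes in 18 of 21 (median -0.64; Vegfa -2.06). NF-kB genes were lower in 19 of 20 (median -0.70, Ccl4 at 4589.7 and 561 CPM, -3.03), and the chemokine Cxcl3 was at 581 and 24.8 CPM (-4.46). Mitochondrially encoded genes were higher in the same SCDi neutrophils (median 0.68). Across the 10 immune classes MHC class II genes stood low in 6 and high in 1, interferon response genes high in 6 and low in 1, dissociation genes low in 7 and high in 1. Hypoxia genes stood low in 5, respiratory chain genes high in 5, and fatty acid oxidation genes apart in 0. In T cells and NK cells, which make little of it, MHC class II transcript was also lower (medians -0.58 and -0.62), but not apart from random lists by the mean of each cell's own CPM (-0.14 and -0.31). In NK cells 47.1% of the vehicle UMIs of H2-Aa and 47.1% of those of H2-Ab1 lay in 1 cell.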

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

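The tests of chromosome shifts within clusters, of the depth of clusters, of the mix of malignant clusters, of chromosome 19, of cycling cells and of the level of RNA from other cells were chosen only after the result was seen.

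Some gene lists stood apart in malignant cells in one direction and in an immune class in the other, and the difference between the classes was not tested. In microglia, cholesterol synthesis (median log2 ratio -0.27), homologous recombination (-0.25), S phase (-0.23) and G2 and M phase genes (-0.14) were lower and matrix and adhesion genes (0.265) higher, each opposite to malignant cells in the main setting. Without doublet removal S phase (0.085, percentile 98.7) and G2 and M phase genes (0.077, percentile 99.2) stood high in microglia, as in malignant cells, and at Leiden resolution 0.5 they had medians of 0.026 and 0.0028 and matrix genes of -0.036. As a mean over clusters the cholesterol synthesis list no longer stood apart (percentile 5.73), nor did homologous recombination without doublet removal (-0.12, percentile 2.97). S phase genes were lower in NK cells (-0.20), but by the mean of each cell's own CPM they were higher (0.22, percentile 97.1). MHC class I genes were lower in malignant cells but higher in macrophages (0.15) and type 2 conventional dendritic cells (0.10), calls lost in macrophages without doublet removal (0.11) and in the dendritic cells by the mean of each cell's own CPM (0.065). Mitochondrially encoded genes were higher in monocytes (0.21), neutrophils (0.68), T cells (0.197) and B cells (0.20). The opposite direction in malignant cells turned as a mean over clusters (0.0038) and in cells without Mki67 or Top2a (0.0495), and with all deposited barcodes B cells turned (-0.0028). NF-kB genes were lower in neutrophils (-0.70) and higher in malignant cells, there without standing apart with no filter on members (0.047). Mesenchymal transition genes were higher in migratory dendritic cells (0.30) but lower with all deposited barcodes (-0.0025), the stricter filter (-0.061), no doublet removal (-0.24, percentile 0.090) and members near their highest class (-0.15), so this opposition to malignant cells rests on the setting.

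Malignant clusters held mostly by 1 library carried a chromosome-wide shift in 7 of 7, as copy number subclones would. The shift was present in the proximal and in the distal genes of the chromosome. Clusters 3, 4, 13, 14, 15 and 18, which were not held mostly by 1 library, met the same limit. Meeting it therefore does not set the 7 apart, and clusters 13, 14 and 15 met it at low depth. Unusual depth was found in 0 of the 7, which argues against the depth of the cells. In 0 of the 3 mostly SCDi clusters with at least 50 vehicle cells did those vehicle cells share the shift. For these 3 clusters that argues against subclones present in both libraries. The mostly SCDi clusters held 55.7% of SCDi malignant cells, and the mostly vehicle cluster 16 held 1.86% of vehicle malignant cells. A different mix of subclones in the pooled animals therefore stays open beside the treatment. The pooling of 3 mice per library keeps the mix and the treatment from being separated.

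Scd2 was higher in malignant cells of the SCDi library after thinning to 10000 UMIs (0.78). Thinning leaves each cell's expected CPM unchanged, so this value cannot decide on the depth of the cells. Chromosome 19 as a whole was near level (0.044), which argues against a gain of chromosome 19 as the whole cause. The mean of Scd2 over clusters was 0.57, and 0.47 over the 10 clusters left without cluster 9, where chromosome 19 differed by 0.23 and Scd2 by 1.52. The mix of clusters and the treatment cannot be told apart for Scd2, because its ratio ranged from -0.16 to 1.52 between clusters and 1 cluster moved the mean below the 0.5 set for excluding the mix. Cholesterol synthesis genes had a median of 0.058 as a mean over clusters, which met the limit set for the mix of clusters. The cluster medians ran from -0.62 to 0.66, with 6 higher and 5 lower. A mean of opposite values cannot tell the mix of clusters from differences within them. The cholesterol synthesis median in cells without Mki67 or Top2a was 0.22, which argues against more cycling cells as the whole cause. It rests on a minority, as 80.3% of vehicle and 90.1% of SCDi malignant cells had a UMI of either gene. Lacking a UMI also depends on depth. In clusters 1 and 8, whose chromosomes differed least between the libraries, Scd2 had log2 ratios of 0.38 and 0.42, hypoxia genes of -0.30 and -0.20 and cholesterol synthesis genes of -0.18 and -0.25. The last were also lower in clusters 0 (-0.19) and 3 (-0.62). An effect of the treatment stays open and was not tested across animals.

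In microglia, MHC class II genes were lower as a mean over clusters 11 and 13 (-0.84), which had at least 50 cells in both libraries. This argues against the mix of those clusters. The homeostatic genes' median was 0.049 in the same mean, with -0.13 in cluster 11 and 0.26 in cluster 13. A mean of opposite values cannot tell the mix of clusters from differences within them. Macrophage and monocyte markers had a median of -0.74 over 15 markers in SCDi microglia, and less RNA or fewer cells of those types would lower them. This median met the limit that was set for RNA from other cells before the result was seen. The markers did not fall alike. Pf4 (-2.28) and Mrc1 (-1.95) were lowest, Ly6c2 (-0.36) and Vcan (-0.19) fell little, and Ms4a4c (0.079) and Ms4a7 (0.19) were higher. The median alone therefore cannot decide on this explanation. The share of such RNA was set by 6 to 12 markers of each of 6 cell classes (macrophages, monocytes, type 2 conventional, migratory and plasmacytoid dendritic cells and B cells). At these shares RNA from other cells could bring a median of 38.9% of the difference in H2-Aa, H2-Ab1, H2-Eb1 and Cd74 (3330 CPM in vehicle and 1060 in SCDi for Cd74). Only markers far below their source level in vehicle microglia were used, which holds the shares down, so the level cannot exclude this explanation. RNA from other cells, border macrophages inside the microglia clusters, a treatment effect and a difference between animals stay open.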

How the results depend on the processing

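The mean over clusters, that mean without clusters that differed on chromosome 19, list members near their highest class, mixed cells kept and Cd79b among the lymphoid genes were tests chosen only after the result was seen. No paired analysis was possible because each group has 1 library and the replicate number 1 is shared by all of them. For the values below the cause was not tested.

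Scd1 and Scd2 were higher in malignant cells under the 8 alternatives run for them, within their interval in 11 of 16 values, with Scd1 at 0.29 and Scd2 at 0.57 as a mean over clusters, at 0.22 and 0.47 over the clusters level on chromosome 19 and Scd2 at 0.78 by the mean of each cell's own CPM. Of 253 list values in malignant cells, 230 stayed on their side of the threshold, 9 no longer stood apart, 12 newly did and 2 reversed. Direction was compared only for the lists that stood apart in the main setting. Of 805 values of named malignant genes 4 reversed and 196 moved past their interval, and of 903 in immune classes 7 reversed and 113 moved. Of 1539 values of immune lists that stood apart, 1303 kept direction and side of the threshold, 196 no longer stood apart and 40 reversed, 14 of these without doublet removal. The 48 counts of lists stayed within 1.5-fold, as did 80 of 84 immune shares within their interval.

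As a mean over clusters, malignant fatty acid oxidation genes no longer stood apart (-0.059), mitochondrially encoded genes (0.0038), Kdelr3 (-0.033), Slc7a11 (0.17), Dnajb11 (-0.021) and Atr (0.0501) reversed, and lipid droplet (-0.12), oxidative stress (0.067), interferon response (0.23), interferon gamma (-0.20), dissociation (-0.13) and costimulation genes (-0.14) newly stood apart. In microglia ATF4 (-0.026), interferon response (-0.042), NF-kB (-0.041) and dissociation genes (-0.00092) reversed, and in T cells ATF4 (-0.084) and homologous recombination genes (-0.18). In malignant cells without Mki67 or Top2a, mesenchymal transition (-0.062), NF-kB (0.11) and respiratory chain genes (0.049) no longer stood apart, mitochondrially encoded genes reversed (0.0495), and ER chaperones (0.10), oxidative stress (0.10), interferon response (-0.14), interferon gamma (-0.27) and LXR genes (0.15) newly stood apart.

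With the mean of each cell's own CPM, malignant respiratory chain genes no longer stood apart (0.061), and microglia ATF4 (-0.0836) and interferon response (-0.011), T cell homologous recombination (-0.0050), NK cell S phase (0.22) and matrix genes (0.0010) reversed. With list members at 20 CPM, malignant fatty acid synthesis (0.082) and oxidation genes (-0.14) no longer stood apart, lipid droplet genes did (-0.26), and B cell homologous recombination genes reversed (-0.029). With no filter on members, malignant NF-kB genes no longer stood apart (0.047) and NK cell matrix genes reversed (0.055). With members near their highest class, classical activation in microglia (0.0096), mesenchymal transition (-0.15) and phagocytosis (-0.11) in migratory dendritic cells and mesenchymal transition in B cells (0.083) reversed.

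With all deposited barcodes, malignant mitochondrially encoded genes no longer stood apart (-0.044), mesenchymal transition genes in migratory dendritic cells (-0.0025), mitochondrially encoded genes in B cells (-0.0028), Nav3 in plasmacytoid dendritic cells (1.18) and Gzmf in T cells (0.18) reversed, and the monocyte share differed by 2.00 points. The stricter filter reversed LXR genes in type 2 conventional dendritic cells (-0.12) and mesenchymal transition genes in migratory dendritic cells (-0.061). Without doublet removal, shares differed by 2.65 points for macrophages, 3.78 for microglia and 1.37 for monocytes. Unnamed clusters held 23.5% of vehicle and 28.3% of SCDi immune cells in this setting, so class membership changed along with the doublets. The same setting reversed S phase (0.085) and G2 and M phase genes (0.077) in microglia, disease-associated (-0.099) and LXR genes (-0.17) in type 2 conventional dendritic cells, and interferon response (-0.024), mesenchymal transition (-0.24), disease-associated (-0.0071) and phagocytosis genes (-0.077) in migratory dendritic cells. In plasmacytoid dendritic cells it reversed p53 (-0.013), interferon gamma (-0.085), classical activation (-0.27) and phagocytosis genes (-0.0020), Cxcl10 (-0.25), Ccl2 (-0.48) and Ccl12 (-0.85), and in B cells lipid droplet (0.17) and oxidative stress genes (0.11) and Slc7a11 (0.36). Leiden resolution 0.5 reversed S phase (0.026), G2 and M phase (0.0028) and matrix genes (-0.036) in microglia, and resolution 2.0 reversed lipid droplet (0.18) and oxidative stress genes (0.12) and Slc7a11 (0.37) in B cells. The cycling share of malignant cells differed by 5.14 points at 1000 UMIs and 12.2 at 5000. Depth limits the classes with few cells, among them neutrophils with 73 and 55.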

Other observations

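T cell subsets were looked at only after the smaller T cell share was seen, and no tests of explanations are reported here. The CD8 coreceptor marks cytotoxic T cells, CD4 marks helper and regulatory T cells, and Foxp3 is the lineage factor of the regulatory ones. Thinned to 2000 UMIs, Cd8a or Cd8b1 had a UMI in 12.4% (9.26 to 16.1; 47 of 379) of vehicle T cells and 20.2% (15.3 to 25.8; 49 of 243) of SCDi T cells, which left out 28 and 6 shallower cells. The unthinned shares were 20.6% and 30.5%, at median depths of 10361 and 10542 UMIs. Cd4 had a UMI in 20.6% (16.6 to 25.0) and 16.05% (11.7 to 21.3) of thinned T cells, unthinned 52.6% and 45.0%. Foxp3 had a UMI in 18.997% (15.2 to 23.3) and 13.6% (9.54 to 18.5), unthinned 34.9% and 29.7%. Gzmb, which encodes granzyme B, had a UMI in 33.0% and 31.3% of thinned T cells (47.7% and 49.0% unthinned). Pdcd1, which encodes the inhibitory receptor PD-1, had a UMI in 13.7% and 16.05% (41.3% and 42.6% unthinned), with overlapping intervals. B cells, which should lack the CD8 coreceptor, had it in 0 of 128 vehicle cells, which allows up to 2.84%, and in 0.870% (1 of 115) of SCDi cells after thinning, at median depths of 6722 and 6393 UMIs.

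Mki67 or Top2a had a UMI in 11.1% (7.86 to 15.1) of vehicle microglia and 10.6% (7.79 to 13.9) of SCDi microglia thinned to 2000 UMIs, unthinned 30.3% and 23.02% at median depths of 20096 and 15432. The share of dividing microglia was not detectably different at this depth. In T cells the thinned shares were 24.3% (20.04 to 28.9) and 20.6% (15.7 to 26.2), unthinned 43.0% and 38.6%, although S phase genes were higher in the summed SCDi T cells. The neutrophil background was 1.45% in vehicle and 0 of 52 cells in SCDi, which allows up to 6.85%, at median depths of 3670 and 4661.

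Within the microglia, the clusters differed from each other. In cluster 11 the median log2 ratio of MHC class II genes was -0.54, of homeostatic genes -0.13, of interferon response genes 0.47, of interferon gamma induced genes -0.35, of MHC class I genes 0.00086 and of cholesterol synthesis genes 0.011. In cluster 13 the medians were -1.17, 0.26, -0.47, -1.31, -0.71 and -0.45 in the same order.

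Among the genes with the lowest malignant ratios, Piwil4 lies at 14696230 to 14740733 and Cryab at 50751325 to 50756636 on chromosome 9, and Bnip3 at 138890836 to 138909519 on chromosome 7 of mm10, all protein coding.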
